A study of Rattus norvegicus with 26 samples.

How the data were processed

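RNA of gubernaculum organ pools, each from a litter, was hybridized to Affymetrix rat arrays after biotin labelling, per the labels. The deposited table holds log2 values for 31099 probe sets on 26 arrays. They were made by the authors with GCRMA in R 2.6.2, per the submitters' processing notes. That method subtracts a background estimated from probe sequence, normalizes arrays to each other by quantiles and gives a value per probe set. The version of GCRMA, and whether all 26 arrays were normalized together, are not given in the sources used here. The log2 scale was read from the values, which ran from 2.16 to 16.4 with close quantiles on all arrays. The median over the tested probe sets was 7.85 to 8.00 per array, and 48.6% to 49.4% of the probe sets stood at 4 or above. Values near the floor carry no order, and a small value after this background correction understates or hides differences.

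Arrays were grouped by the strain and age in their titles, giving 5 LE and 7 ORL arrays at GD17 and 6 LE and 6 ORL arrays at GD19. The labels give the strain of 2 further GD19 arrays as unknown, and the series text says that they appeared to have been mixed up. They entered no fit and are given as values only. Replicates were pools of separate litters. Both hybridization batches held arrays of all groups, with 3 of each in batch 1 and 2, 4, 3 and 3 in batch 2.

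From the deposited values, 57 control probe sets were removed, and a probe set was tested if it stood at 4 or more on at least 5 of the 24 arrays, which left 15746. The platform table names a single gene for 12535 of these, several for 305 and none for 2906. Symbols were checked through Entrez numbers against the RefSeq genes of GRCr8 for 12501 of the probe sets with a single gene, and 0 changed. A gene (9610 in all, 2237 with several probe sets) was represented by its probe set with the highest mean. Rxfp2, set in advance to be named, had no probe set with a single symbol and was not analysed here. Esr1 and Insl3 stood at the floor on every array and were not tested.

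Limma (3.58.1 in R 4.3.3) was fitted to the 24 arrays with a mean per group and the batch as a fixed effect, with 19 residual degrees of freedom and default empirical Bayes settings (prior degrees of freedom 2.64). Contrasts were ORL minus LE at each age, GD19 minus GD17 in each strain, and their interaction. All were two-sided with Benjamini-Hochberg adjustment over the 15746 probe sets and a threshold of 0.05. The batch term itself was called for 615 probe sets. Beside each fold against a group below 4 on all arrays, a bound was computed with 4 for the dim group.

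Before the data were examined, 24 gene lists were fixed: sarcomere, slow fibre, fast fibre, excitation-contraction coupling and neuromuscular junction, myogenic regulators, smooth muscle, Hox and limb patterning factors, Wnt, hormone receptors and steroid enzymes, androgen and glucocorticoid induced genes, BMP and TGF-beta, hedgehog with retinoic acid and Notch, collagens and matrix, cell cycle, and oxidative phosphorylation, and markers of erythroid cells, macrophages and leukocytes, endothelium, nerve and Schwann cells, epithelium, mesothelium, testis, cartilage with bone and tendon, and fat. Lists can share members: many fast and slow fibre genes are also in the sarcomere or the coupling list, so the muscle lists are not independent results. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Calls of list members were also adjusted over the list alone. Camera passed 7, 10, 12, 10 and 6 lists in the 5 comparisons. With a correlation estimated from the data none passed (lowest adjusted p 0.427, 0.290, 0.0923, 0.180 and 0.353), so every list call rests on the preset value. The directional test fry, which does not compare a list with other genes, passed 8, 11, 13, 14 and 8. Of the lists that camera passed, fry also passed 6, 8, 11, 10 and 6 and did not pass 1, 2, 1, 0 and 0. Overlaps of calls were tested with Fisher's exact test.

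Genes were named by a rule set at the same time: up to 10 largest rises and 10 largest falls among called genes with the same sign in both batches, up to 4 called members of each list by smallest adjusted p, 5 in each direction for the interaction, and a fixed set of genes whatever their values, which included Rxfp2, Esr1, Insl3, Myod1, Myog, Acta1, Bmp3, Wnt4, Hoxa10 and Fkbp5. The text names part of the genes that the rule allows, and those fixed genes for the comparisons in which their values bear on a list.

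The alternatives set in advance were median centring and quantile normalization of the arrays, no filter or a filter at 6, no batch term, batch as a random block, each batch alone, replicate number as a block, only the groups compared, a trended robust variance, array weights, a single probe set or the mean per gene, stricter thresholds, estimated correlation and fry for lists, and leaving out each array. After the data were seen, 7 more were added: leaving out 3 sets of arrays that stood apart, the 3' minus 5' value of beta-actin as a covariate, the trend with gene span removed from each array, and the slope on gene span as a covariate in 2 versions. Gene span is the length on the chromosome from RefSeq GRCr8, known for 9605 of 9610 genes. It is not the transcript length, which was not analysed here. The slope is that of an array's deviations from the mean over arrays on log10 of span. It was taken from genes outside all lists, and from all probe sets as the other version. Both versions had been tried before the first was chosen.

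The steps were tested on simulated data with some probe sets changed by known amounts. The simulated probe sets varied independently, with no floor and no arrays standing apart, so the shares recovered hold for simpler data than these. At a log2 change of 1, 89.6%, 85.1%, 88.1%, 91.0% and 65.7% were recovered in the 5 comparisons, and at 0.5 40.3%, 47.8%, 49.3%, 64.2% and 28.4%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.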

Results

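Gene expression was measured with Affymetrix rat arrays in the fetal gubernaculum, the cord of mesenchyme and muscle that joins the fetal testis to the abdominal wall and guides its descent. RNA came from pools of organs, each pool from a litter, of Long Evans (LE) rats and of ORL rats, a strain with inherited cryptorchidism (undescended testes). The pools were taken at gestational day 17 (GD17) and gestational day 19 (GD19). There were 5 arrays of LE and 7 of ORL at GD17, 6 of LE and 6 of ORL at GD19, and 2 GD19 arrays whose strain the labels give as unknown and which entered no comparison. All 4 groups were spread over 2 hybridization batches. Of 31099 probe sets, 15746 were bright enough to be tested, and they stood for 9610 genes. An array had 29.6% to 31.7% of its probe sets at the floor of the scale (2.16 on the log2 scale). The number of arrays, not a depth, limits the precision. Arrays of the same group correlated between 0.987 and 0.997, and none was a copy of another (the smallest SD of a difference was 0.306 on the log2 scale). Without repeat hybridizations these values cannot tell whether the same RNA was used on 2 arrays. Pairs across groups and the arrays of unknown strain were not checked in this way.

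On the first principal component, which held 36.4% of the variance, the GD17 arrays lay below 0 and the GD19 arrays above 0, with an exception at each age. LE_GD17 replicate 4 lay at 23.3 and ORL_GD19 replicate 4 at -21.4. Hbz, an embryonic globin that fell with age in both strains, stood at 9.61 in LE_GD17 replicate 4, below the 11.02 to 13.91 of the other 4 LE arrays at GD17. In ORL_GD19 replicate 4 it stood at 10.7, above the 4.44 to 9.63 of the other 5 ORL arrays at GD19.

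The first comparison asked how the gubernaculum of the cryptorchid strain differed from that of LE at GD17 (7 ORL and 5 LE arrays; log2 differences are ORL minus LE, ± the SE of the limma fit). Zp2, a glycoprotein of the egg coat, was higher in ORL by 4.51 ± 0.23 (7.31 ± 0.19 in ORL against 2.78 ± 0.56 in LE, mean ± SD). Ano3, a membrane protein of the anoctamin family, was higher by 3.68 ± 0.15, and Pard6g, a cell polarity protein, by 3.92 ± 0.17. Crh, the corticotropin-releasing hormone, was higher by 3.97 ± 0.34, the pancreatic lipase Pnlip by 3.17 ± 0.62, Nup62cl by 3.04 ± 0.38 and the nicotinic receptor subunit Chrna5 by 2.87 ± 0.34. Lower in ORL were Cntn3, a contactin of neural cell adhesion (-4.06 ± 0.21), the matrix protein Fndc1 (-2.74 ± 0.45), the tetraspanin Tspan18 (-2.56 ± 0.36), the peroxisomal membrane protein Pxmp4 (-2.55 ± 0.20) and ceruloplasmin, Cp, a copper-carrying ferroxidase (-2.13 ± 0.25). The highest limma adjusted p among these 12 genes was 0.00115. Some groups were dim on every array (below 4 on the log2 scale), so that only a bound can be given: taking 4 for the dim group, Zp2 was at least 9.95-fold, Ano3 at least 3.93-fold and Chrna5 at least 2.09-fold higher, and Cntn3 at least 6.26-fold, Tspan18 at least 3.47-fold and Cp at least 1.62-fold lower.

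Genes of striated muscle were lower in ORL at GD17. The muscle lists below share many members, so that here and in the later comparisons their counts and tests are not independent. Of 41 measured sarcomere genes, 21 were lower and 0 higher (24 lower when adjusted over the list alone), with a median of -0.62 (camera adjusted p = 2.34e-09, and adjusted p = 0.6248 with an estimated correlation). They included the slow and embryonic myosin heavy chains Myh7 (-1.55 ± 0.24) and Myh3 (-1.13 ± 0.17), nebulin, Neb, which sets thin filament length (-2.09 ± 0.36), and Myom1 of the M-band (-0.90 ± 0.19). The skeletal alpha-actin Acta1 was lower by -0.43 ± 0.10. Of 28 genes of excitation-contraction coupling and the neuromuscular junction, 10 were lower and 0 higher (also 10 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 2.93e-06, and adjusted p = 0.6248 with an estimated correlation). Among them were Ryr1, the calcium release channel (-2.13 ± 0.43), the calcium channel subunit Cacna2d1 (-0.78 ± 0.16), the acetylcholine receptor subunit Chrna1 (-0.71 ± 0.13) and Lrp4, a receptor for agrin (-1.04 ± 0.23). Of 16 fast fibre genes 7 were lower (also 7 adjusted over the list alone; camera adjusted p = 0.0037, and adjusted p = 0.6248 with an estimated correlation). With fry the fast fibre list did not pass (fry adjusted p = 0.0567). Of 15 slow fibre genes 2 were lower, and that list did not pass (camera adjusted p = 0.104). It did in batch 1 alone (median -0.10, camera adjusted p = 0.0392) and not in batch 2 (-0.22, 0.353). Of 23 myogenic regulators 5 were lower and 1 higher (the same numbers adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.0114, and adjusted p = 0.6248 with an estimated correlation). They included the cadherin Cdh15 (-0.64 ± 0.12) and the growth factor binding protein Igfbp5 (-1.71 ± 0.29), while Myod1 (-0.31 ± 0.12) and Myog (-0.16 ± 0.11) did not pass (adjusted p = 0.0593 and 0.316). Without the array LE_GD17 replicate 4, which stood near the GD19 arrays, the median was -0.34 for the sarcomere list, -0.29 for the coupling list and -0.16 for the myogenic regulators, which then no longer passed (camera adjusted p = 0.102). That list also did not pass without LE_GD17 replicate 3 (median -0.25, camera adjusted p = 0.0517).

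Collagen and matrix genes were lower in ORL at GD17, 30 of 61 against 2 higher (38 and 2 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 2.34e-09, and adjusted p = 0.6248 with an estimated correlation). Lower members included the fibrillar collagen Col5a1 (-1.29 ± 0.22), the basement membrane protein Nid2 (-0.89 ± 0.14) and the protease Adamts1 (-0.88 ± 0.10). Osteoglycin, Ogn, was among the higher ones (1.31 ± 0.17). Of 19 hormone receptors, their cofactors and steroid enzymes, 6 were lower and 0 higher (8 lower adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.00102, and adjusted p = 0.427 with an estimated correlation), or -0.18 without LE_GD17 replicate 4. These were led by the prolactin receptor Prlr (-1.80 ± 0.30), the nuclear receptor cofactors Ncor1 (-0.86 ± 0.17) and Ncoa1 (-0.78 ± 0.15) and the thyroid hormone receptor Thra (-0.71 ± 0.15). Genes of oxidative phosphorylation were higher, 15 of 48 against 1 lower (the same adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.00926, and adjusted p = 0.671 with an estimated correlation). Ndufa5 (0.56 ± 0.09) and Ndufa4 (0.40 ± 0.07), both of the respiratory chain, were among them. Across genes, which are not independent replicates, the strain difference fell with the span of the gene on the chromosome (Spearman -0.27). Its median was 0.14 in the shortest of 5 equal classes of genes by span and -0.12 in the class with the longest. The median span was 51.0 kb for the collagen list, 80.0 kb for the hormone receptor list, 9.85 kb for the oxidative phosphorylation list and 24.4 kb for all genes. The slope of an array's values on span averaged -0.11 ± 0.070 in the 7 ORL arrays and 0.060 ± 0.031 in the 5 LE arrays (SD, log2 per 10-fold span; exact permutation p = 0.00379, adjusted p = 0.0173 over 12 tests). With that slope as a covariate, a test added after the data were seen, the mean over the collagen list moved from -0.52 ± 0.15 to -0.09 ± 0.14 and no longer passed, and the median of the oxidative phosphorylation list turned to -0.01. The mean over the hormone receptor list went from -0.38 ± 0.06 to -0.33 ± 0.08.

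Among the remaining lists at GD17, 15 of 54 cell cycle genes were higher and 4 lower without a shift of the list (camera adjusted p = 0.101), with the replication inhibitor geminin, Gmnn, higher (0.46 ± 0.09) and thymidine kinase, Tk1, lower (-1.003 ± 0.12). The list passed in batch 1 alone (median 0.20, camera adjusted p = 0.00604) and not in batch 2 (0.02, 0.798). Smooth muscle genes were lower in 7 and higher in 0 of 18, and that list did not pass (median -0.09, camera adjusted p = 0.0614), though it did in batch 1 alone (-0.22, 0.0266, against -0.12 and 0.164 in batch 2). Nor did the Wnt, Hox and hedgehog lists pass (camera adjusted p = 0.44, 0.598 and 0.673). BMP and TGF-beta genes went both ways, 7 higher and 7 lower of 39, with a median of -0.02, a mean of 0.01 and a camera direction of down that did not pass (adjusted p = 0.598). Bmp4 (0.72 ± 0.17, or 0.45 without LE_GD17 replicate 4) and Id2, a target of BMP signals (0.62 ± 0.10), were higher. Markers of macrophages and leukocytes were higher in 6 of 23 cases, among them the chemokine Ccl6 (1.30 ± 0.32) and lysozyme, Lyz2 (0.88 ± 0.22), and the list did not pass (camera adjusted p = 0.126). In batch 1 alone it passed (median 0.75, camera adjusted p = 0.00244), and in batch 2 it lay at -0.12 (0.929). Of 10 nerve and Schwann cell markers 4 were lower, among them the neurofilaments Nefm (-2.20 ± 0.42) and Nefl (-1.93 ± 0.34), and the list did not pass (median -0.01, camera adjusted p = 0.135).

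In all, 2265 probe sets were higher and 1761 lower in ORL at GD17 by limma with Benjamini-Hochberg adjustment (4026 of 15746). Of these, 355 differed by at least 2-fold, 123 higher and 232 lower. Without LE_GD17 replicate 4 the count was 2656. Within the hybridization batches alone it was 613 and 586, of which 355 and 226 were higher. With the slope on gene span as a covariate it was 415. Within batch 1 and batch 2 the median was -0.41 and -0.61 for the sarcomere list, -0.38 and -0.51 for the coupling list, -0.37 and -0.82 for collagens, -0.17 and -0.41 for hormone receptors and 0.13 and 0.18 for oxidative phosphorylation. The fast fibre list did not pass in batch 2 (-0.46, camera adjusted p = 0.0559). Other probe sets of Igfbp5 (4 of 4), Neb (1 of 1), Tk1 (1 of 1) and Thra (1 of 1) were not called, and 1 of 3 other probe sets of Ogn was called the opposite way.

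**Figure D1:**
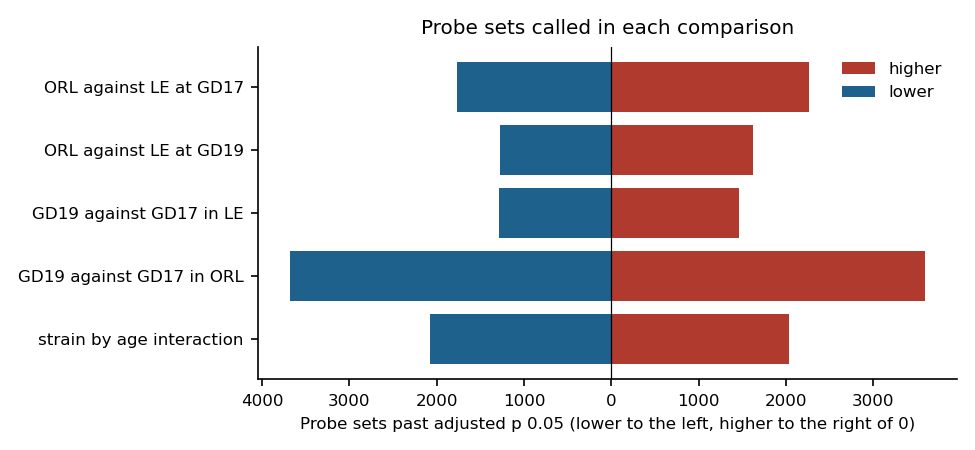
Bars show, for each of the 5 comparisons, the number of probe sets past an adjusted p of 0.05, with lower ones to the left and higher ones to the right of 0. The change with age in ORL has the longest bars (3595 higher and 3677 lower).

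At GD19 the same question was asked of 6 ORL and 6 LE arrays. Ano3 was again higher in ORL, by 4.33 ± 0.15, as were Zp2 (3.75 ± 0.22) and Pard6g (3.74 ± 0.17). Abca1, a transporter that exports cholesterol, was higher by 3.47 ± 0.31, the B cell chemokine Cxcl13 by 2.06 ± 0.35, the mast cell protease Mcpt10 by 2.06 ± 0.70 and Rrp9, which takes part in ribosomal RNA processing, by 1.93 ± 0.26. Cntn3 was again lower (-2.83 ± 0.21), with Pxmp4 (-2.48 ± 0.20) and Cp (-2.09 ± 0.25). Also lower were Sprr1a, a protein of the cornified envelope (-2.67 ± 0.52), the X-linked homeobox gene Rhox5 (-2.42 ± 0.24), Mfsd10, of a transporter superfamily (-2.26 ± 0.29) and the microfibril protein Mfap5 (-2.19 ± 0.73). Limma adjusted p was 0.0438 for Mcpt10 and 0.0412 for Mfap5, and 0.0015 or lower for the other 12. As bounds against a dim group taken as 4, Ano3 was at least 5.93-fold and Zp2 at least 5.71-fold higher, and Cntn3 at least 3.11-fold, Rhox5 at least 2.89-fold and Cp at least 2-fold lower.

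Striated muscle genes were lower in ORL at GD19 too. Of 28 genes of excitation-contraction coupling and the neuromuscular junction, 16 were lower and 0 higher (19 lower adjusted over the list alone), with a median of -0.61 (camera adjusted p = 5.68e-08, and adjusted p = 0.455 with an estimated correlation). The fetal acetylcholine receptor subunit Chrng was lower by -1.18 ± 0.22, Chrna1 by -0.79 ± 0.13, alpha-sarcoglycan, Sgca, by -0.99 ± 0.23 and the calcium channel subunit Cacng6 by -0.97 ± 0.17. Of 41 sarcomere genes 7 were lower and 0 higher (6 lower adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.00027, and adjusted p = 0.513 with an estimated correlation). Among them were Tmod4, which caps thin filaments (-1.28 ± 0.27), and the small heat shock protein Cryab (-0.71 ± 0.21), while Acta1 did not pass (-0.15 ± 0.10, adjusted p = 0.317). Of 16 fast fibre genes 5 were lower (also 5 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 0.0015, and adjusted p = 0.513 with an estimated correlation), including the Z-disc protein Myoz1 (-1.41 ± 0.42) and the calcium store protein Casq1 (-1.37 ± 0.42). Of 15 slow fibre genes 5 were lower and 0 higher (5 and 1 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.0207, and adjusted p = 0.513 with an estimated correlation). With fry the sarcomere and slow fibre lists did not pass at GD19 (fry adjusted p = 0.111 and 0.0600). Myogenic regulators were lower in 8 of 23 cases and higher in 1 (10 and 1 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.00367, and adjusted p = 0.455 with an estimated correlation). Vgll2, a cofactor of muscle transcription (-1.49 ± 0.25), Trim54 (-1.004 ± 0.24), the methyltransferase Smyd1 (-0.79 ± 0.15) and Myog (-0.33 ± 0.11, adjusted p = 0.0363) were lower, and Myod1 did not pass (-0.27 ± 0.12, adjusted p = 0.11).

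Single arrays decided some of these muscle results. The slow fibre list did not pass without LE_GD19 replicate 6 (median -0.29, camera adjusted p = 0.0618), ORL_GD19 replicate 1 (-0.38, 0.0516) or ORL_GD19 replicate 4 (-0.28, 0.0600). Without ORL_GD19 replicate 4, which lay toward the GD17 arrays, the sarcomere median was -0.17 and the fast fibre median -0.24, and the latter was -0.25 without LE_GD19 replicate 6. Cryab and Myoz1 did not pass without LE_GD19 replicate 4, LE_GD19 replicate 6 or ORL_GD19 replicate 4 (values closest to 0 of -0.55 and -1.10), nor Casq1 without any of these or ORL_GD19 replicate 1 (-1.04). Myog did not pass without any 1 of LE_GD19 replicates 1, 3 and 6 and ORL_GD19 replicates 1, 3, 4 and 5 (-0.28). Outside the muscle lists, Mfap5 did not pass without any 1 of LE_GD19 replicates 1, 2, 4 and 6 and ORL_GD19 replicates 1, 4, 5 and 6 (-1.82). Mcpt10 did not pass without any 1 of LE_GD19 replicates 2, 3, 4 and 6, ORL_GD19 replicates 1, 2, 5 and 6 and ORL_GD17 replicates 5, 6 and 7 (1.64).

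Lists of Wnt, of BMP and TGF-beta, and of Hox and limb patterning genes were higher in ORL at GD19, while that of hedgehog, retinoic acid and Notch genes did not pass (4 of 22 higher, median 0.12, camera adjusted p = 0.0884). Of 40 Wnt pathway genes 14 were higher and 1 lower (the same adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000114, and adjusted p = 0.29 with an estimated correlation). They included the Wnt inhibitor Apcdd1 (1.36 ± 0.22), the ligand Wnt4 (0.94 ± 0.22), the secreted antagonist Sfrp2 (0.77 ± 0.12) and the receptor Fzd1 (0.64 ± 0.09). Of 39 BMP and TGF-beta genes 9 were higher and 2 lower (13 and 2 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.000139, and adjusted p = 0.29 with an estimated correlation). Higher members were Inhba, a subunit of activin (1.41 ± 0.20), Bmp4 (0.80 ± 0.16) and the inhibitory Smad7 (0.75 ± 0.13), and Bmp3 did not pass (0.31 ± 0.22, adjusted p = 0.356). Of 29 Hox and limb patterning factors 8 were higher and 1 lower (12 and 1 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.000139, and adjusted p = 0.381 with an estimated correlation). Tbx18 (1.08 ± 0.15) and Twist1 (0.74 ± 0.15), transcription factors of mesenchyme, were higher, and Hoxa10 did not pass (0.21 ± 0.08, adjusted p = 0.0769).

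Collagen and matrix genes were higher in ORL at GD19, 16 of 61 against 1 lower (17 and 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 1.37e-07, and adjusted p = 0.475 with an estimated correlation). Fibronectin, Fn1 (0.94 ± 0.19), the protease Adamts9 (0.93 ± 0.14), the crosslinking enzyme Loxl1 (0.43 ± 0.09) and Ogn (1.495 ± 0.17) were higher. Oxidative phosphorylation genes were lower, 23 of 48 against 0 higher (28 lower adjusted over the list alone), with a median of -0.20 (camera adjusted p = 1.46e-09, and adjusted p = 0.29 with an estimated correlation), as in Ndufs3 (-0.50 ± 0.11), Idh3a (-0.48 ± 0.09) and Uqcrc1 (-0.30 ± 0.06). In smooth muscle 4 of 18 genes were higher, among them the contractile regulators Mylk (0.78 ± 0.12) and Cnn1 (0.55 ± 0.12), without a shift of the list (camera adjusted p = 0.0884). Hormone receptors went both ways, 2 higher and 2 lower, with a median of -0.03 and a camera direction of up that did not pass (adjusted p = 0.937). The glucocorticoid receptor Nr3c1 was higher (0.24 ± 0.07), and Ramp1 (-0.96 ± 0.23) and the growth hormone receptor Ghr (-0.63 ± 0.14) were lower. Fkbp5, which steroid hormones induce, did not pass (-0.03 ± 0.09, adjusted p = 0.865). Tk1 (-0.90 ± 0.12), Nefm (-1.57 ± 0.41) and Nefl (-1.27 ± 0.33) were lower, as at GD17. Here the strain difference rose with gene span across genes (Spearman 0.30), from a median of -0.10 in the shortest class to 0.14 in the longest. The slope on span averaged 0.11 ± 0.049 in the 6 ORL arrays and -0.039 ± 0.095 in the 6 LE arrays (SD; exact permutation p = 0.00433, adjusted p = 0.0173 over 12 tests). With the slope as a covariate, added after the data were seen, the mean over the collagen list moved from 0.35 ± 0.14 to -0.06 ± 0.14 (SE) and its median to -0.08, and the mean over the oxidative phosphorylation list from -0.26 ± 0.05 to -0.11 ± 0.04.

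**Figure D2:**
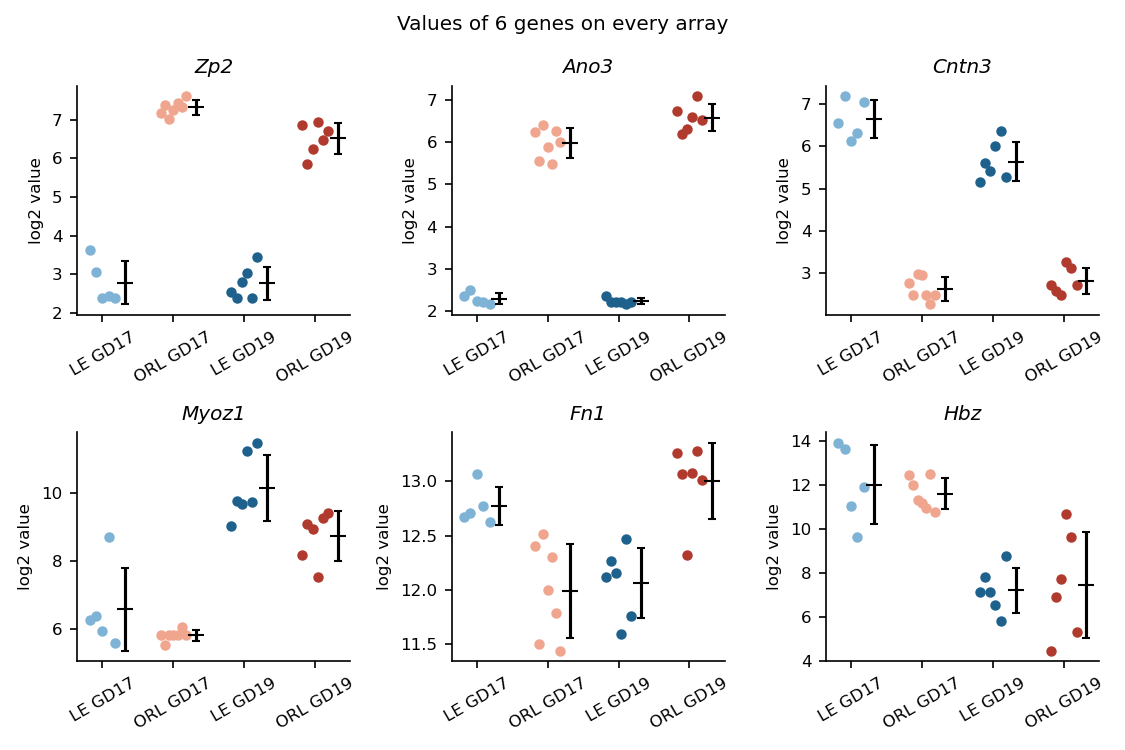
Each point is the log2 value of a gene on an array, by strain and age, and the black mark and bar beside each group give its mean and SD. Zp2 and Ano3 stand higher and Cntn3 lower in ORL at both ages, and a single LE array at GD17 stands apart for Myoz1 (8.72).

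At GD19, 1621 probe sets were higher and 1269 lower in ORL by limma (2890 of 15746, 281 of them by at least 2-fold, 151 higher and 130 lower). Without LE_GD19 replicate 6 the count was 1859, and 1088 without LE_GD19 replicates 4 and 6, which lay apart on the second principal component (14.0% of the variance). Without both, the median was 0.18 for collagens, with 5 genes higher, 0.14 for BMP and TGF-beta and 0.18 for Wnt, with 6 genes higher each. The slow (-0.25, camera adjusted p = 0.130) and fast fibre lists (-0.16, 0.0832) then did not pass, nor did Mcpt10, Mfap5, Sgca, Cryab, Myoz1, Casq1, Trim54, Myog, Wnt4 and Ramp1 (adjusted p from 0.0779 to 0.310). The excess of higher probe sets was not kept with median centring (1508 of 3017) or quantile normalization (1504 of 3025), nor by gene (878 higher and 944 lower, or 794 of 1778 with the mean of probe sets). Within the batches alone it was 370 and 910, and 418 with the slope on gene span as a covariate. Within batch 1 and batch 2 the median was -0.28 and -0.92 for the coupling list and -0.13 and -0.39 for the sarcomere list, which did not pass in batch 1 (camera adjusted p = 0.104). Nor did the fast fibre (-0.08, 0.192), slow fibre (-0.14, 0.230) and myogenic regulator (-0.22, 0.0517) lists pass there, and in batch 2 their medians were -0.69, -0.66 and -0.33. It was 0.13 and 0.29 for Wnt, 0.16 and 0.35 for BMP and TGF-beta, 0.18 and 0.68 for collagens and -0.13 and -0.30 for oxidative phosphorylation. The other probe set of Inhba and of Ghr was not called, nor was 1 of 2 of Abca1, and 1 of 3 other probe sets of Ogn was called the opposite way here too.

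**Figure D3:**
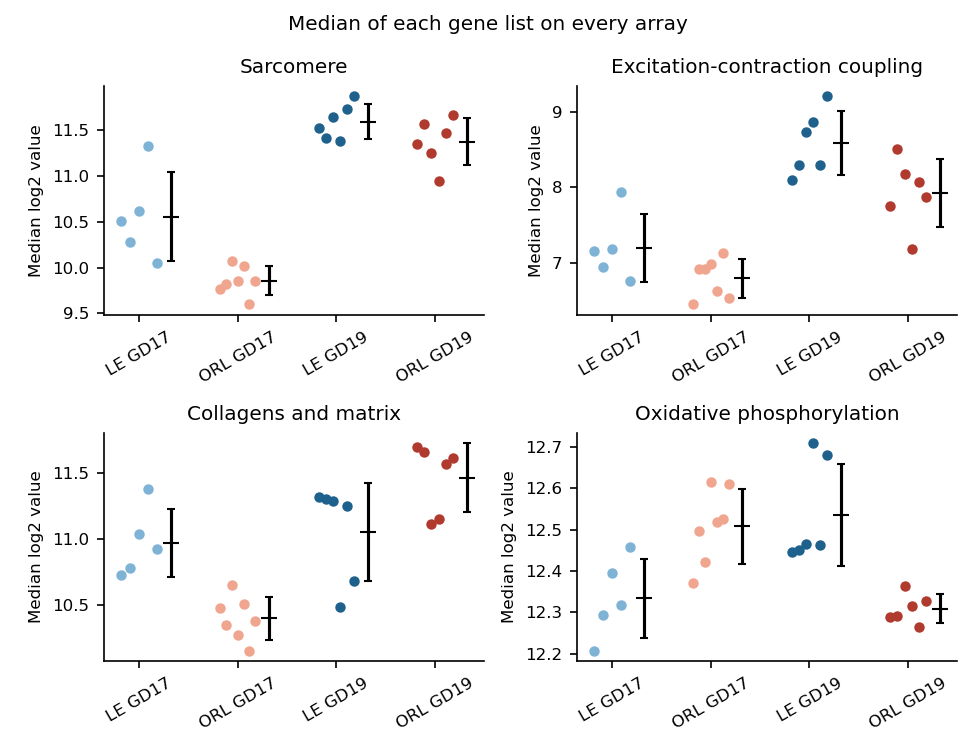
Each point is the median log2 value of a gene list on an array, by strain and age, and the black mark and bar give the group mean and SD. Sarcomere and excitation-contraction genes stand higher at GD19 than at GD17 in both strains, and the collagen median is lowest in ORL at GD17.

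The third comparison asked how the LE gubernaculum changed from GD17 (5 arrays) to GD19 (6 arrays). Sprr1a rose by 4.10 ± 0.55 and Loricrin by 3.69 ± 0.87. The mitochondrial creatine kinase of sarcomeres, Ckmt2, rose by 3.71 ± 0.53, the phospholipase Pla1a by 3.66 ± 0.74, Mfap5 by 3.53 ± 0.77, Myoz1 by 3.51 ± 0.45 and the perinatal myosin Myh8 by 2.80 ± 0.46. The embryonic globin Hbz fell (-4.81 ± 0.93), as did the globin Hbg1 (-2.59 ± 0.63), the neuronal GTPase Rit2 (-2.87 ± 0.48) and Abca1 (-2.29 ± 0.33). The highest limma adjusted p among these 11 genes was 0.00714. Against a dim group taken as 4, Sprr1a rose at least 8.27-fold and Loricrin at least 7.3-fold, and Rit2 fell at least 2.5-fold.

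Muscle genes rose together in LE. Of 41 sarcomere genes 36 rose and 0 fell (37 and 1 adjusted over the list alone), with a median of 1.11 (camera adjusted p = 3.24e-26, and adjusted p = 0.0923 with an estimated correlation). Acta1 rose by 0.65 ± 0.11. In the coupling and junction list 25 of 28 rose (26 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 3.25e-19, and adjusted p = 0.0923 with an estimated correlation), as in muscle creatine kinase, Ckm (1.99 ± 0.27), and caveolin, Cav3 (1.67 ± 0.22). Fast fibre genes rose in 14 of 16 cases (camera adjusted p = 1.95e-12, and adjusted p = 0.0923 with an estimated correlation) and slow fibre genes in 10 of 15 (camera adjusted p = 3.17e-10, and adjusted p = 0.0923 with an estimated correlation). Myogenic regulators rose in 13 of 23 (camera adjusted p = 3.72e-07, and adjusted p = 0.0949 with an estimated correlation), including Myf6 (1.47 ± 0.23) and Myog (0.73 ± 0.11). Smooth muscle genes rose in 7 of 18 and fell in 1 (camera adjusted p = 0.0107, and adjusted p = 0.261 with an estimated correlation). Oxidative phosphorylation genes rose in 16 of 48 with 0 falling (camera adjusted p = 3.49e-07, and adjusted p = 0.223 with an estimated correlation), among them the muscle form Cox6a2 (1.74 ± 0.23). Adjusted over the list alone, 14 fast fibre genes, 13 slow fibre genes, 13 myogenic regulators, 8 smooth muscle and 22 oxidative phosphorylation genes rose.

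Patterning and signalling lists fell with age in LE. Hox and limb factors fell in 13 and rose in 5 of 29 cases, with a median of -0.30 (camera adjusted p = 0.000727, and adjusted p = 0.232 with an estimated correlation). Twist1 (-1.02 ± 0.15) and Hoxa10 (-0.46 ± 0.09) fell and Hoxd8 (0.83 ± 0.13) rose. Wnt genes fell in 12 and rose in 4 of 40, with a median of -0.13 (camera adjusted p = 0.00266, and adjusted p = 0.223 with an estimated correlation), as in Wnt4 (-1.33 ± 0.23) and Sfrp2 (-0.71 ± 0.13). BMP and TGF-beta genes fell in 9 and rose in 2 of 39, with a median of -0.24 (camera adjusted p = 0.00274, and adjusted p = 0.168 with an estimated correlation), including Bmp3 (-1.29 ± 0.23) and Ltbp1, which binds latent TGF-beta (-1.0 ± 0.17). Hedgehog, retinoic acid and Notch genes fell in 7 and rose in 1 of 22, with a median of -0.20 (camera adjusted p = 0.00266, and adjusted p = 0.0949 with an estimated correlation), such as Stra6, the retinol transporter (-0.98 ± 0.17), and Gli2 (-0.57 ± 0.13). Adjusted over the list alone, 17 Hox and limb, 15 Wnt, 12 BMP and TGF-beta and 7 hedgehog, retinoic acid and Notch genes fell. Erythroid markers fell in 4 of 19 (5 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 0.000176, and adjusted p = 0.436 with an estimated correlation). With fry the erythroid list did not pass (fry adjusted p = 0.0700). Collagens did not pass, with 8 rising and 4 falling (median 0.09, camera adjusted p = 0.463), nor did hormone receptors (median 0.02, camera adjusted p = 0.416), among which Ramp1 rose (1.67 ± 0.24). Fkbp5 rose by 0.43 ± 0.09. The erythroid median was -0.39 without LE_GD17 replicate 1 and -1.32 without LE_GD17 replicate 3, the Wnt median -0.08 without LE_GD17 replicate 5, and the BMP median -0.13 and -0.15 without LE_GD17 replicate 5 and without LE_GD19 replicate 6, or -0.05 without LE_GD19 replicates 4 and 6.

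In LE 1465 probe sets rose and 1287 fell by limma (2752 of 15746, 500 of them by at least 2-fold, 345 rising and 155 falling). The rising share was 53.2%, and 1427 of 2871 rose with median centring, and by gene 1086 rose and 757 fell. With only the LE arrays in the fit the count was 1480. The 3' minus 5' log2 value of beta-actin was lower at GD19 by 0.49 (exact permutation p = 0.0390, adjusted p = 0.117 over 12 tests), and with it as a covariate, added after the data were seen, the count was 1367. Batch 2 alone, where LE_GD17 replicate 4 was 1 of 2 LE arrays at GD17, called 5, and batch 1 alone 2211. The median in batch 1 and batch 2 was 1.15 and 1.04 for the sarcomere list and 1.07 and 1.30 for the coupling list, and 0.36 and -0.28 for the collagen list, which passed in both, in opposite directions (camera adjusted p = 0.00256 and 0.0393). For BMP and TGF-beta it was 0.02 and -0.21, where the test passed as down in both (camera adjusted p = 0.0192 and 0.00471). With the slope on gene span as a covariate the mean over the collagen list was 0.43 ± 0.12 instead of 0.17 ± 0.15. The erythroid median was -1.51 in batch 1 and -0.14 in batch 2, where the list did not pass (camera adjusted p = 0.549).

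The fourth comparison was the same step in ORL (7 arrays at GD17 and 6 at GD19). Fndc1 rose by 4.89 ± 0.43, the mast cell tryptase Tpsab1 by 4.26 ± 0.62, Myh8 by 4.01 ± 0.43, Pla1a by 3.82 ± 0.68, Ryr1 by 3.49 ± 0.41 and the matrix protein Thbs2 by 3.21 ± 0.32. Crh (-5.22 ± 0.32), Pnlip (-5.06 ± 0.59), Hbz (-4.16 ± 0.85) and the tight junction protein Cldn11 (-3.19 ± 0.40) fell. The highest limma adjusted p among these 10 genes was 0.000479. Against a dim group taken as 4, Crh fell at least 11.2-fold and Tpsab1 rose at least 7.15-fold. The size of the fall of Pnlip depends on the floor too, since its ORL arrays at GD19 stood at 2.65 to 2.93 except replicate 4 (5.23).

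Muscle lists rose in ORL as well. Of 41 sarcomere genes 38 rose and 1 fell (39 and 1 adjusted over the list alone), with a median of 1.42 (camera adjusted p = 2.14e-20, and adjusted p = 0.18 with an estimated correlation), including Myh7 (2.46 ± 0.23), the myosin-binding Mybpc1 (2.02 ± 0.20) and Acta1 (0.93 ± 0.10). In the coupling and junction list 25 of 28 rose (27 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 3.52e-11, and adjusted p = 0.18 with an estimated correlation), as in Ckm (2.41 ± 0.25). Fast fibre genes rose in 14 of 16 (camera adjusted p = 9.33e-08, and adjusted p = 0.18 with an estimated correlation), slow fibre genes in 12 of 15 (camera adjusted p = 6.04e-06, and adjusted p = 0.18 with an estimated correlation) and myogenic regulators in 15 of 23 (camera adjusted p = 0.000134, and adjusted p = 0.21 with an estimated correlation), each with 1 member falling and with the same numbers adjusted over the list alone. Myog rose by 0.55 ± 0.10. Smooth muscle genes rose in 13 of 18 (also 13 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 1.54e-06, and adjusted p = 0.18 with an estimated correlation), among them the smooth muscle myosin Myh11 (2.32 ± 0.28) and Synpo2 (1.11 ± 0.12).

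Collagen and matrix genes rose in ORL in 51 of 61 cases and fell in 1 (the same adjusted over the list alone), with a median of 1.02 (camera adjusted p = 3.23e-16, and adjusted p = 0.18 with an estimated correlation). The laminin chain Lama2 rose by 2.56 ± 0.25 and Col5a1 by 2.02 ± 0.21. Hormone receptors rose in 11 of 19 and fell in 1 (12 and 1 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.00107, and adjusted p = 0.18 with an estimated correlation), such as Ncoa1 (1.13 ± 0.14), Thra (1.01 ± 0.14) and the growth factor receptor Igf1r (0.89 ± 0.12). Oxidative phosphorylation genes fell in 23 of 48 and rose in 4 (23 and 5 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.0116, and adjusted p = 0.677 with an estimated correlation), as in Ndufa4 (-0.51 ± 0.07). Erythroid markers fell in 4 of 19 (also 4 adjusted over the list alone), with a median of -1.04 (camera adjusted p = 0.0147, and adjusted p = 0.716 with an estimated correlation). That list did not pass without ORL_GD17 replicate 1 (-0.67, camera adjusted p = 0.0793) or ORL_GD19 replicate 1 (-0.73, 0.0762). Cell cycle genes went both ways, 10 rising and 14 falling of 54, with a median of -0.03, a mean of 0.05 and a camera direction of down that did not pass (adjusted p = 0.685). The proliferation marker Mki67 rose (1.95 ± 0.28) and Gmnn fell (-0.65 ± 0.08). Wnt, BMP and TGF-beta, Hox and hedgehog lists did not shift (camera adjusted p = 0.357, 0.548, 0.779 and 0.548). Hoxa10 (-0.47 ± 0.08) and Bmp3 (-0.96 ± 0.21) fell, Fkbp5 rose (0.42 ± 0.09), and Wnt4 did not pass (-0.05 ± 0.21, adjusted p = 0.852). The change with age rose with gene span across genes in ORL (Spearman 0.27) and fell in LE (-0.17). The slope on span differed between the ages in ORL (exact permutation p = 0.000583, adjusted p = 0.00699) and not past the threshold in LE (0.0519, adjusted 0.125). With the slope as a covariate, added after the data were seen, the median of the oxidative phosphorylation list in ORL turned to 0.03. Its mean, which lay near 0 without the covariate (-0.04 ± 0.05), turned to 0.18 ± 0.05. The mean over the collagen list went from 1.04 ± 0.14 to 0.46 ± 0.16.

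In ORL 3595 probe sets rose and 3677 fell by limma (7272 of 15746, 1014 of them by at least 2-fold, 785 rising and 229 falling). The near balance depends on the scaling, with 3293 of 7516 rising with median centring and 3324 of 7409 with quantile normalization, and by gene 2278 rose and 2530 fell. Batch 1 and batch 2 alone called 3713 and 3900, and the fit with the slope on gene span 1106. For age in LE the fit with that slope called 1859. Within the batches the median was 1.56 and 1.31 for the sarcomere list, 1.18 and 0.90 for the coupling list, 0.86 and 1.13 for collagens, 0.45 and 0.28 for hormone receptors and -0.13 and -0.24 for oxidative phosphorylation, which did not pass in batch 1 (camera adjusted p = 0.108). For erythroid markers it was -1.75 and -0.50, and they did not pass in batch 2 (camera adjusted p = 0.202).

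**Figure D4:**
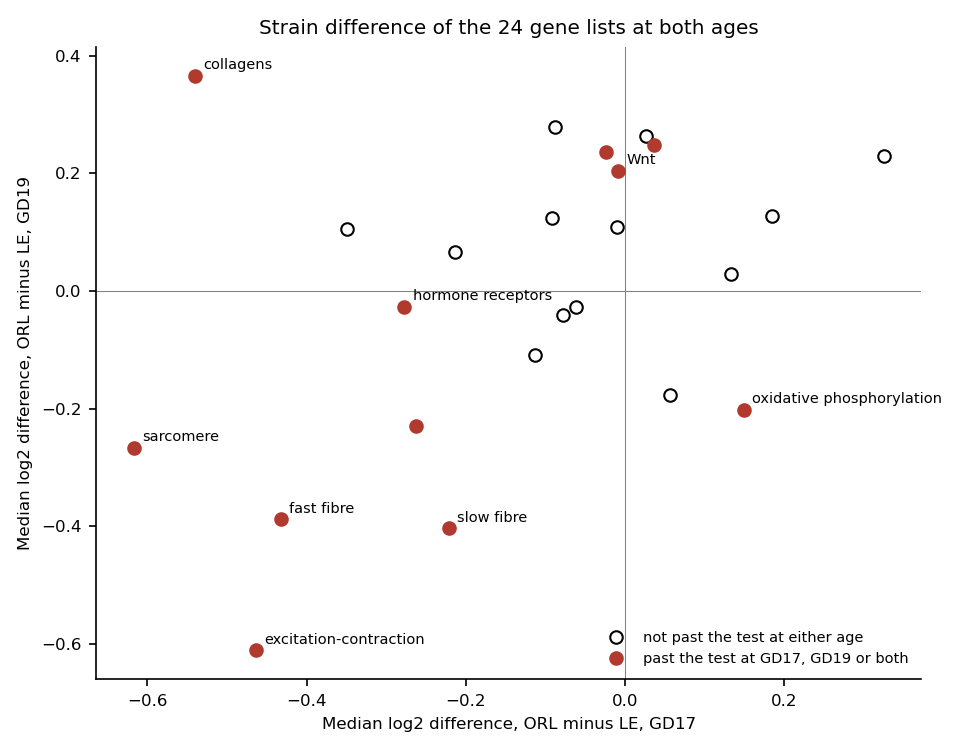
Each point is a gene list, with the median ORL minus LE log2 difference at GD17 on the horizontal axis and at GD19 on the vertical axis, and filled points passed the camera test with a preset correlation at an age. Sarcomere and excitation-contraction genes lie below 0 at both ages, collagens go from -0.54 to 0.37 and oxidative phosphorylation from 0.15 to -0.20.

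The interaction asked whether the strain difference changed between the ages (GD19 minus GD17 of ORL minus LE; a positive value means a higher ORL level, relative to LE, at GD19). Fndc1 (2.95 ± 0.63), the matrix protein Emilin3 (2.36 ± 0.47), Neb (2.29 ± 0.50), the collagen chain Col6a2 (2.20 ± 0.57) and the synaptic scaffold Shank1 (2.19 ± 0.37) had the highest values by the rule for named genes. Crh (-3.92 ± 0.48), Pnlip (-2.78 ± 0.87), Nup62cl (-2.28 ± 0.53), Sprr1a (-2.25 ± 0.75) and Mlf1 (-2.10 ± 0.43) were below 0. The sizes for Crh, Pnlip and Sprr1a depend on the floor of the scale: at GD19 Crh stood at 2.20 ± 0.02 in LE and 2.25 ± 0.08 in ORL and Pnlip at 2.75 ± 0.21 in LE, and at GD17 Sprr1a at 2.95 ± 0.58 in LE and 2.51 ± 0.22 in ORL (mean ± SD). Limma adjusted p was 0.0309 for Sprr1a, 0.0225 for Pnlip and 0.00763 or lower for the other 8. Sprr1a did not pass without LE_GD17 replicate 1 or 5, LE_GD19 replicate 4 or 6 or ORL_GD19 replicate 4 (-1.75), nor did Pnlip without LE_GD17 replicate 4 (-2.06, adjusted p = 0.0550). With the slope on gene span as a covariate the Sprr1a value was 0.30.

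The collagen and matrix list had a positive interaction in 41 of 61 genes and a negative one in 0 (46 and 1 adjusted over the list alone), with a median of 0.96 (camera adjusted p = 2.16e-14, and adjusted p = 0.353 with an estimated correlation). Fn1 (1.70 ± 0.28), Fbln2 (1.30 ± 0.21), Nid2 (1.21 ± 0.20) and Loxl1 (0.86 ± 0.12) were among them. For oxidative phosphorylation 29 of 48 were negative and 0 positive (31 and 1 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 9.54e-09, and adjusted p = 0.353 with an estimated correlation), including Ndufa5 (-0.77 ± 0.13) and Sdhc (-0.58 ± 0.12). Wnt genes were positive in 12 and negative in 1 of 40 (13 and 1 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.00248, and adjusted p = 0.353 with an estimated correlation), among them Wnt4 (1.28 ± 0.32). BMP and TGF-beta genes were positive in 10 and negative in 1 of 39 (12 and 1 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.0103, and adjusted p = 0.353 with an estimated correlation), or 0.35 without LE_GD17 replicate 4. Ltbp1 was one of them (1.17 ± 0.24). Smooth muscle genes were positive in 6 of 18 (also 6 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0103, and adjusted p = 0.353 with an estimated correlation). Hormone receptors were positive in 5 of 19 (also 5 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.0276, and adjusted p = 0.353 with an estimated correlation), as in Ncor1 (1.19 ± 0.24) and Ncoa1 (1.18 ± 0.21). Their median was 0.05 and did not pass without LE_GD17 replicate 4 (camera adjusted p = 0.0695), and it was 0.09 without ORL_GD17 replicate 4 or ORL_GD19 replicate 5.

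For the sarcomere and coupling lists the interaction did not pass (medians 0.16 and -0.19, camera adjusted p = 0.0662 and 0.865), with 5 and 3 positive members and 1 negative member each. The sarcomere list passed in batch 1 alone (0.22, camera adjusted p = 2.66e-05) and not in batch 2 (0.11, 0.651), and it passed without LE_GD19 replicates 4 and 6 (0.22). Ttn, titin, the molecular spring of the sarcomere (2.10 ± 0.54), Myh7 (1.80 ± 0.34) and Myh3 (1.21 ± 0.24) were positive. Nor did the cell cycle list pass (camera adjusted p = 0.392), in which Cenpf was positive (1.60 ± 0.31) and Gmnn negative (-0.69 ± 0.12), although it passed in batch 1 alone (-0.25, 0.000682; 0.09 and 0.266 in batch 2), nor that of hedgehog, retinoic acid and Notch genes (camera adjusted p = 0.241), in which Gli2 was positive (1.19 ± 0.17). Fast fibre, erythroid and endothelial lists had a median and mean below 0 and a camera direction of up, and none of these passed (adjusted p = 0.865 for each).

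The interaction was called for 2030 probe sets above 0 and 2076 below (4106 of 15746, 625 of at least 2-fold, 509 above and 116 below). This balance was not kept by gene (1210 above and 1613 below, or 1178 of 2913 above with the mean of probe sets), with median centring (1974 of 4268 above) or in batch 2 alone (1199 of 1913). Across genes it rose with gene span (Spearman 0.38), from a median of -0.24 in the shortest class to 0.24 in the longest. With the slope on span as a covariate, added after the data were seen, limma called 0 probe sets, with 946 at an unadjusted p below 0.05. The mean over the collagen list then moved from 0.87 ± 0.20 to 0.03 ± 0.24 and that over the oxidative phosphorylation list from -0.35 ± 0.07 to -0.04 ± 0.07. Among the probe sets called without it, the median size was 0.63 and became 0.22, while the median SE over the tested probe sets went from 0.18 to 0.28. Batch 1 alone called 2 and batch 2 alone 1913. Within them the collagen median was 0.58 and 1.40, that of oxidative phosphorylation -0.28 and -0.42, that of Wnt 0.23 and 0.45, and that of BMP and TGF-beta 0.25 and 0.25. Smooth muscle (0.36 and 0.31) and hormone receptors (0.08 and 0.22) did not pass in batch 2 (camera adjusted p = 0.0777 and 0.0649).

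**Figure D5:**
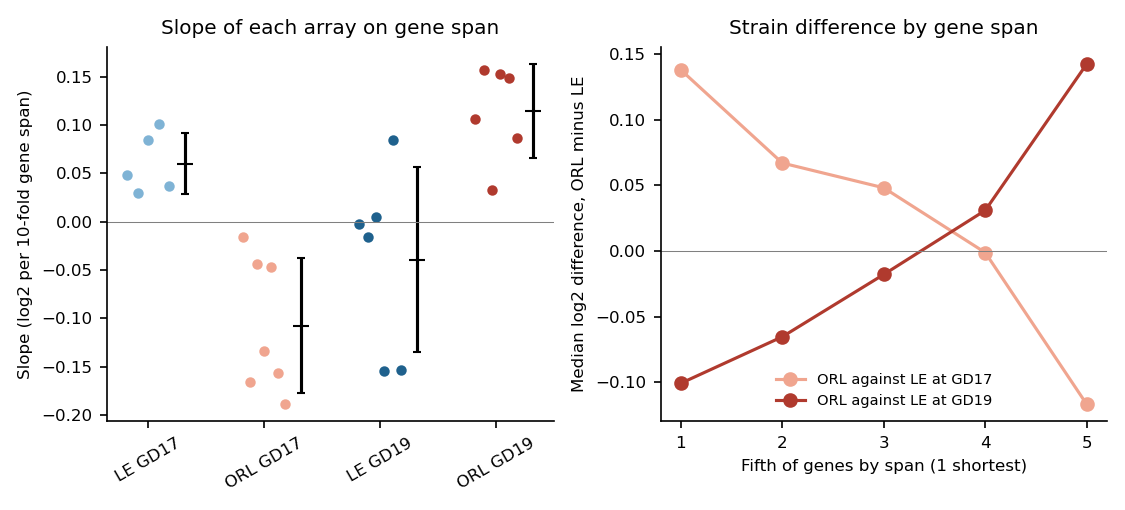
The left panel shows the slope of each array's values on gene span (log2 per 10-fold span) by group, with the mean and SD as black marks, and the right panel shows the median ORL minus LE log2 difference in 5 equal classes of the genes by span. The difference falls from 0.14 to -0.12 with span at GD17 and rises from -0.10 to 0.14 at GD19.

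The last question was how far the calls were shared, with genes represented by a single probe set each. At both ages 153 genes were higher in ORL, where independent lists of these sizes would share 147.8 (Fisher's exact test p = 0.636), and 136 were lower, where 110.7 would be shared (p = 0.00896). In opposite directions at the 2 ages 331 genes were called, 183 higher and then lower (158.9 in independent lists) and 148 lower and then higher (103.0). These became 63 without LE_GD19 replicates 4 and 6, 2 with the slope on gene span as a covariate and 1 at 2-fold. The strain calls shared in the same direction also became fewer with that covariate and at 2-fold, as given with the alternatives below. Across genes the 2 strain differences correlated weakly (Pearson 0.11, Spearman -0.09). Ano3, Zp2 and Pard6g were among the shared higher genes and Cntn3, Pxmp4 and Cp among the shared lower ones. Of 77 genes with a shared strain difference and further probe sets, 20 (26.0%) had another probe set called the same way, against 79 of 203 (38.9%) for age changes shared by both strains. The changes with age overlapped more, with 536 genes rising in both strains (257.4 in independent lists, Fisher's exact test p = 3.39e-86) and 339 falling in both (199.3, p = 3.91e-30). In opposite directions 153 genes were called, 97 (285.9 in independent lists) and 56 (179.4), and the correlation across genes was 0.50 (Pearson) and 0.29 (Spearman). These pairs of comparisons share no array, though they share the batch term and the estimate of spread. The Fisher tests count genes, which are not independent replicates, so their p-values do not measure the spread between litters.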

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

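Tests of the slope on gene span, of the stage of the whole fetus, of the muscle share in its present form and of the arrays between the ages were chosen only after the results were seen.

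For 6 gene lists the strain difference at GD19 minus that at GD17 passed the camera test with a preset correlation, and for none with an estimated one: collagens and matrix (median 0.96), smooth muscle (0.32), Wnt (0.27), BMP and TGF-beta (0.23), hormone receptors (0.15) and oxidative phosphorylation (-0.36). For single genes the same difference passed limma. Among matrix genes it was 2.95 for Fndc1, 2.36 for Emilin3, 2.20 for Col6a2, 1.70 for Fn1, 1.30 for Fbln2, 1.21 for Nid2 and 0.86 for Loxl1. Among muscle genes it was 2.29 for Neb, 2.10 for Ttn, 1.80 for Myh7 and 1.21 for Myh3. Among signalling genes it was 1.28 for Wnt4, 1.19 for Gli2, 1.19 for Ncor1, 1.18 for Ncoa1 and 1.17 for Ltbp1. Shank1 had 2.19 and the cell cycle gene Cenpf 1.60. Below 0 were Crh (-3.92), Pnlip (-2.78), Sprr1a (-2.25), Nup62cl (-2.28), Mlf1 (-2.10), Ndufa5 (-0.77), Gmnn (-0.69) and Sdhc (-0.58), with sizes that depend on the floor of the scale for Crh, Pnlip and Sprr1a. Sprr1a did not pass without any 1 of 5 arrays (-1.75 at the closest to 0), nor Pnlip without LE_GD17 replicate 4 (-2.06), nor the hormone receptor list without that array (0.05).

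In 38 of 434 tests (8.76%) an array stood far from the others of its group, in 10.4% of the tests of genes and 3.12% of those of lists, where chance gives about 1 in 20. On LE_GD17 replicate 4 these were Pla1a (9.08), Myf6 (10.68), Myom1 (11.02), Cdh15 (10.78), Myoz1 (8.72), Ckmt2 (6.45), Ramp1 (10.43), Hoxd8 (9.66), Adamts1 (11.89), Cenpf (9.02) and Thra (6.82) above the other 4 arrays, Abca1 (6.19), Rit2 (2.81) and Ltbp1 (10.94) below them, and the medians of slow fibre genes (11.38) and of androgen and glucocorticoid induced genes (9.33) above them. On ORL_GD19 replicate 4 they were Nup62cl (7.06) and Pnlip (5.23) above the others, and Pla1a (4.77), Sprr1a (2.19), Cacng6 (3.66), Cxcl13 (7.31) and Fkbp5 (8.44) below. ORL_GD19 replicate 3 was low for Fn1 (12.32), Ltbp1 (10.69) and Nid2 (12.05), and ORL_GD19 replicate 1 for Vgll2 (4.13). LE_GD19 replicate 3 was low for epithelial markers (median 7.31) and Nup62cl (4.12), and LE_GD19 replicate 5 was low for Rrp9 (3.61) and high for Pxmp4 (8.01). LE_GD19 replicate 6 was low for Hoxa10 (10.78). Pnlip on LE_GD19 replicate 6 (3.18), Tpsab1 on ORL_GD17 replicate 6 (3.23), Crh on LE_GD19 replicate 3 (2.16) and Ano3 on LE_GD19 replicate 1 (2.36) met the rule too, but all arrays of these groups were dim for these genes (below 4), so that the flags say little. LE_GD17 replicate 5 was low for Col6a2 (8.27) and ORL_GD17 replicate 2 high for Ccl6 (7.57).

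Outside the comparisons, the first GD19 array of unknown strain had Ano3 at 7.53, Zp2 at 7.09 and Pard6g at 9.26. The highest LE array at GD19 stood at 2.36, 3.45 and 5.76, and the second array of unknown strain at 2.22, 2.38 and 5.50.

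Collagen and matrix genes were lower in ORL at GD17 (median -0.54) and higher at GD19 (0.37), with a median interaction of 0.96. A linear trend of the arrays with gene span as the whole cause is argued against by a median of 0.87 after its removal, with 35 of 41 calls kept, and RNA integrity as beta-actin shows it by 0.96 with that covariate. An axis between arrays that runs with gene span remains a candidate explanation: with the slope as a covariate the median was 0.032 and the mean over the list went from 0.87 ± 0.20 to 0.03 ± 0.24 (SE), so that the call ended because the value itself fell, with a spread only somewhat larger. The same axis ran within groups, where over 24 arrays with group and batch removed the slope and the list mean correlated (r = 0.73, permutation p = 0.0001, adjusted p = 0.0004 over 5 lists, Spearman 0.72, permutation p = 0.00028, and r = 0.67 without the 2 arrays farthest out); the hormone receptor list, with a longer median span (80.0 kb against 51.0 kb), did not follow it (r = 0.22, adjusted p = 0.381), so that span alone does not tell which list follows. What the axis is stays open, as does a biological difference between the strains and ages, since the slope itself differs between the groups.

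Striated muscle genes were lower in ORL at both ages (excitation-contraction medians -0.46 and -0.61), which may come from several sources. Part of the difference moved with the 2 arrays between the ages. Without LE_GD17 replicate 4 the GD17 medians were -0.29 for coupling genes and -0.34 for sarcomere genes (-0.62 with it). Without ORL_GD19 replicate 4 the GD19 sarcomere median was -0.17 (-0.27 with it). These lists still passed camera (adjusted p = 0.000325, 9.1e-07 and 0.00941). A trend with gene span is argued against by a median of -0.44 after its removal at the age closer to 0. An earlier stage of the whole ORL fetus at GD17 is argued against by Hbz minus an adult alpha globin of -0.16 ± 0.42 (SE) in ORL minus LE. At least 1.15 was set as needed, and a smaller lag is not excluded. At GD19 that difference was 1.01 ± 0.84 (exact permutation p = 0.299), in the direction of an earlier ORL stage, which stays open there. The globin value varied more between ORL arrays at GD19 (SD 1.91) than between LE arrays (0.73). ORL_GD19 replicate 4 had the highest Hbz of the ORL arrays at GD19 (10.7), and the difference without it was not tested. The axis with gene span is argued against at GD17 (median -0.64 with the slope as a covariate, mean from -0.57 ± 0.18 to -0.71 ± 0.24) and stays open at GD19 (median -0.43, mean from -0.60 ± 0.17 to -0.46 ± 0.24, within 2 SE of 0). Within groups no relation of the slope to the muscle lists was seen (coupling r = -0.20, sarcomere r = -0.01, permutation adjusted p = 0.430 and 0.942). The sarcomere mean at GD19 went from -0.32 ± 0.17 to -0.31 ± 0.23 with the slope as a covariate. A lower share of muscle in the pools cannot be told apart: sarcomere genes were less lowered than the coupling genes at GD19 (by 0.28, permutation p = 0.00449), but they stand at higher levels, and within 3 classes of level, a form chosen after that result, the gap was 0.15 (permutation p = 0.173). A first form of this test asked only whether collagens, which fibres do not carry, lay below -0.2 at GD17, as they did (-0.54), and was dropped because that value was -0.09 with the slope as a covariate, and the strain itself stays untested.

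On a scale from the GD17 mean (0) to the GD19 mean (1) of its strain, LE_GD17 replicate 4 lay at 0.78 (the other 4 between -0.27 and -0.03) and ORL_GD19 replicate 4 at 0.48 (the other 5 between 1.00 and 1.18), both in batch 2. A swap between the ages among the 24 arrays of the groups is argued against, since the lowest LE array at GD19 lay at 0.83 and the highest ORL array at GD17 at 0.11. The 2 GD19 arrays of unknown strain were not placed on this scale, so a swap with them was not tested. An array of the other strain is argued against by strain positions of -0.09 and 1.05. A litter of another stage remains a candidate explanation: Hbz, left out of the scale, put LE_GD17 replicate 4 at 0.55 and was lower there (9.61) and higher in ORL_GD19 replicate 4 (10.7) than in every other array of the group. A single wrong label or a mixed pool was not tested.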

How the results depend on the processing

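The 7 alternatives that leave out arrays standing apart or use beta-actin or gene span were chosen after the data were seen. Among 182 values of named genes, none called with or without an alternative changed direction, except under the slope on gene span. There Sprr1a in the interaction turned to 0.30. Changes of direction of values called in neither fit were not counted. No batch term and batch as a random block changed 0 calls of these genes, and centring or quantile normalization made 1 stronger each. Each batch alone ended 65 and 80 calls, and the slope covariate 88 (75 with the slope over all probe sets). Of 120 list results, median centring and the mean of probe sets changed the call of none, quantile normalization ended 3 and brought 1, and no batch term brought 1. A filter at 6 left 175 of the gene values and 115 of the list results. For the rest the cause was not tested. The floor of the signal affects the values of genes dim in a group, and bounds were computed only between 2 groups, not for interactions.

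Leaving out each array in turn gave 2656 to 4161 probe sets for the strain at GD17, 1859 to 3263 at GD19, 2139 to 3174 for age in LE, 6249 to 7429 for age in ORL, 3207 to 4483 for the interaction and 44 to 49 list shifts (45 with all arrays). Of 4368 values of named genes 42 became weaker and 3 stronger, and of 2880 of lists 8 and 29.

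Replicate numbers did not pair the arrays: deviations of same-numbered arrays had a median correlation of -0.145 (6 of 33 pairs above 0.1), against -0.041 for other numbers, so arrays did not as a rule correlate best with their own number. With a replicate block the counts were 2983, 2587, 2158, 6557 and 3213 in the 5 comparisons, with 46 list shifts.

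In batch 1 alone 613 probe sets were called for the strain at GD17, 370 at GD19, 2211 for age in LE, 3713 for age in ORL and 2 for the interaction, and in batch 2 alone 586, 910, 3900 and 1913, and 5 for age in LE. A batch holds fewer arrays, and why the 2 batches differed was not tested. In batch 2 alone the list medians for age in LE turned to -0.28 for collagens and -0.12 for the cell cycle, and in batch 1 alone that of BMP and TGF-beta was 0.02 while its test stayed down. The cell cycle list at GD19 did not pass with all arrays (camera adjusted p = 0.649). It passed as higher in ORL in batch 2 alone (median 0.12, camera adjusted p = 0.0129) and not in batch 1 (-0.07, 0.0829). With only the groups compared, age in LE called 1480. With the mean of all probe sets of a gene, which tests fewer features, GD19 called 1778 and age in ORL 4822. A log2 difference of at least 1 left 355, 281, 500, 1014 and 625, and 40 and 188 shared strain and age calls. An adjusted p below 0.01 left 2015, 1191 and 1335 for the first 3 comparisons and 1887 for the interaction, with 104 and 432 shared. With an estimated correlation 0 lists passed camera (45 with the preset one, and 54 with fry), and the mixed form of fry, which counts changes in either direction, passed 97.

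Without LE_GD19 replicates 4 and 6, 1088 were called at GD19, 1784 for age in LE and 2662 for the interaction. Without the 4 arrays that stood apart, GD19 called 1103, the interaction 2334, and 174 strain calls were shared. Without the 2 arrays between the ages the counts were 2709, 2469, 3135, 7427 and 3115. With beta-actin as a covariate age in LE called 1367 and 502 age calls were shared. With the trend on gene span removed GD19 called 1850 and the interaction 2633.

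With the slope on gene span as a covariate 415 were called at GD17, 418 at GD19, 1106 for age in ORL and 0 for the interaction (946 at an unadjusted p below 0.05), and 57 strain and 378 age calls were shared. With the slope over all probe sets these were 556, 585, 1646 and 6, with 73 and 477 shared. The covariate differs between the groups, so that it takes up part of any group difference and raises the SE (median 0.28 against 0.18 for the interaction). The sizes fell too, with a median over the reported calls from 0.47 to 0.30 at GD17, 0.49 to 0.30 at GD19, 0.50 to 0.31 for age in ORL and 0.63 to 0.22 for the interaction. With the former, medians turned to -0.0080 for oxidative phosphorylation at GD17 and 0.031 for age in ORL, to -0.081 for collagens at GD19 and to -0.041 for the cell cycle at GD19, which passed camera (adjusted p = 0.0487). With the latter that for oxidative phosphorylation and age in ORL was -0.0052 while the test turned to up.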

Other observations

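The tests of the probe variant, of skin and of other splits of the arrays were set before their results were seen, and the comparison of the strain difference with the change in age was chosen after. Markers of tissues that could lie beside the gubernaculum did not pass camera as lists with all arrays. The test fry, which does not compare a list with other genes, passed some of them: epithelial markers at GD17 (fry adjusted p = 0.0358), with age in LE (0.0405) and in the interaction (0.0131), testis markers at GD17 (0.0198), at GD19 (0.0109), with age in ORL (0.000193) and in the interaction (0.0014), fat markers with age in LE (0.0164), and mesothelial (0.00166) and nerve markers (0.00965) with age in ORL. At GD17 endothelial markers were higher in 4 and lower in 1 of 20 (median 0.19, camera adjusted p = 0.422). Epithelial markers were higher in 2 and lower in 5 of 11 (median -0.35, camera adjusted p = 0.126) and mesothelial markers in 3 and 3 of 16 (median -0.21, camera adjusted p = 0.422). At GD19 testis markers were lower in 1 of 5 (median -0.18, camera adjusted p = 0.191), cartilage, bone and tendon markers higher in 1 of 9 (median 0.26, camera adjusted p = 0.191) and fat markers lower in 1 of 9 (median -0.11, camera adjusted p = 0.229). In ORL, 4 endothelial markers rose and 7 fell with age (median -0.28, camera adjusted p = 0.548). Genes induced by androgens and glucocorticoids rose in 10 and fell in 2 of 25 with age in ORL (median 0.09, camera adjusted p = 0.0701), and were higher in ORL than LE in 5 at GD19 (median -0.03, mean 0.09, camera adjusted p = 0.42).

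Where members of a list went both ways, its median, mean and test could differ in sign without any of them passing. At GD19 nerve and Schwann cell markers had a median of 0.11 and a mean of -0.15 and mesothelial markers 0.07 and -0.01, both with a camera direction of up (adjusted p = 0.922 and 0.559). With age in LE the nerve list had a median of 0.18 and a mean of 0.03 with a direction of down (adjusted p = 0.956). Cartilage, bone and tendon markers had a median of 0.01 and a mean of -0.27 with a direction of down for age in ORL (adjusted p = 0.908), and 0.30 and -0.09 with a direction of up for the interaction (adjusted p = 0.748).

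On the 2 GD19 arrays of unknown strain the genes with the 3 largest rises and falls at GD17 that were also called the same way at GD19 were read as values only, with Cp, which was picked by hand before that rule. Cntn3 stood at 2.47 on the first and 5.20 on the second array, where LE arrays at GD19 ran from 5.17 to 6.36 and ORL arrays from 2.47 to 3.25. Pxmp4 stood at 5.65 and 5.02 (LE 7.58 to 8.01, ORL 4.92 to 5.67) and Cp at 3.54 and 5.35 (LE 4.50 to 5.57, ORL 2.45 to 3.54). Over 289 genes called the same way at both ages, on a scale with 0 for the LE mean and 1 for the ORL mean, the first array lay at 1.12 and the second at 0.08. On the second array Pxmp4 lay in the ORL range, and Ano3, Zp2, Pard6g, Cntn3 and Cp within the LE range. Tspan18 told the strains apart less, at 2.16 and 2.74, below both the LE arrays (2.86 to 6.43) and the ORL arrays (3.08 to 4.85). The sarcomere median was 10.8 and 11.4, that of excitation-contraction genes 7.17 and 8.10, that of collagens 11.3 and 11.2 and that of oxidative phosphorylation 12.4 and 12.5. No array was assigned to a group.

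Of 100 splits of the arrays for each comparison, 1 called as many probe sets, the real one. This makes chance alone unlikely for all 5 counts, but 100 splits cannot exclude it, and they do not tell what the counts come from. The real split and the highest of the others were 4026 and 584 for the strain at GD17, 2890 and 953 at GD19, 2752 and 1317 for age in LE, 7272 and 3637 for age in ORL, and 4106 and 383 for the interaction.

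The strain difference at GD17 was set beside the change with age in LE across genes, where a lag of ORL would give a correlation below 0. The strain difference and the change with age in LE correlated at -0.09 (Pearson) and 0.02 (Spearman). They share the LE arrays at GD17, which alone gave 0.56 and 0.53 in simulations with no effect. With these arrays split between the 2 differences in 10 ways, the medians were -0.12 (from -0.41 to 0.11) and -0.03 (from -0.25 to 0.17), so that a lag is neither shown nor excluded.

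A variant between the strains under the probes of a probe set may account for part of the strain differences shared by both ages. Another probe set of the gene was called the same way in 26.0% of 77 such genes against 38.9% of 203 with shared age changes (Fisher's exact test p = 0.0501), which leaves this open, and among differences of at least 2-fold the shares were 63.6% of 11 and 72.7% of 33 (p = 0.706). Of cornified envelope genes Sprr1a was lower in ORL at GD19 (-2.67 ± 0.52), Loricrin (-1.96 ± 0.82, adjusted p = 0.102) and Krt10 (-0.88 ± 0.57, adjusted p = 0.298) did not pass, and skin on some LE pools might bring the difference. Of 7 keratinocyte genes set for that test only Krt15 and Dsp were measured (median 0.23), too few to decide.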
